A study of Arabidopsis thaliana with 19 samples.

How the data were processed

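Chromatin immunoprecipitation with sequencing (ChIP-seq) was made from Arabidopsis thaliana inflorescences that express VENUS-tagged DNA-methylation reporters, per the labels. The mCG reporter (mCGBP-VENUS) binds CG methylation and the mCHH reporter (mCHHBP-VENUS) binds CHH methylation, and MBD6 and SUVH9 were taken as their source genes before the data were examined. Full-length SUVH9-VENUS was pulled down with GFP-Trap and the reporters with an anti-GFP antibody, per the labels. Each of the 19 files holds coverage: the deposited values are read depths per base as whole numbers, not scaled to library size. CASAVA 1.8.2, Bowtie or Bowtie2, bedtools and the build TAIR10 are named, with no parameters, per the submitters' processing notes. Duplicate removal, read extension and the handling of reads that map to several places are not recorded there. The Bowtie files hold nuclear chromosomes only.

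Mean depth was computed over each of 37899 genes of a table of the assembly TAIR10.1, of which 27444 are protein-coding and 3917 are of the pseudogene biotype, the class under which the table lists known retroelement genes. The table names another assembly than the files, so none of its coordinates are given, and positions come from the files. As a check of the gene positions, input depth was averaged around both gene ends in equal sections of each chromosome, and its minimum lay outside the genes in all sections. The table was used without strand, so flanks are 1 kb on both sides of a gene.

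Values are log2 of gene depth over mean nuclear depth plus 0.1. Genes with an input depth of 0.25 to 4 times the nuclear mean were tested. Groups were compared with limma 3.58.1 in R 4.3.3, with trend and robust options and Benjamini-Hochberg adjustment at 0.05, within the libraries of 1 aligner, whose groups share an estimate of the spread. Fixed gene lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation. Single libraries were given as values, with list medians placed among 10000 random lists of matched depth. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated data for mCG_WT against WT input over 37622 genes, the fit recovered 0 of 50 genes shifted by 0.3 log2, 5 of 50 shifted by 0.6, 31 of 50 shifted by 1 and 41 of 50 shifted by 2, with 2 false calls among 79. The simulated noise was normal and independent between genes, with a spread pooled over mCG_WT, mCHH_WT and inputs.

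The named genes were set by a rule written before the data were examined. In tested comparisons they are up to 8 protein-coding genes and 5 pseudogenes per direction with the largest change among genes past the threshold, with library values of the groups that do not overlap and a length of at least 500 bp. With 1 library they are up to 5 per class and direction with the same direction against both wild-type (WT) replicates. Members of the fixed lists (DNA methylation machinery, loci known for methylation-dependent silencing, imprinted genes, ONSEN retrotransposons, housekeeping genes, floral and reproductive regulators, reporter source genes and the pseudogene biotype) are named where a list is described.

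Depth steps and equal bases were compared over all 171 pairs of files, in 20175 bins of 1 kb where both alignments of the inputs agree. The 4 Bowtie2 input files share reads with the 2 Bowtie inputs and were summed into 2 libraries. The 2 files labelled MBD_WT differed by about the sampling noise, with correlated depth steps, and were counted as 1 sample. The planned limma tests of MBD_WT were therefore replaced by values. The library labelled mCHH_cmt2 holds the reads of mCG_WT replicate 2 and was not used as a sample of its own. Summing left 16 libraries, a count that still includes the one labelled mCHH_cmt2 and holds the WT inputs under both aligners. The labels do not say whether replicates come from separate plants, so p-values measure only the spread between these samples. Alternatives covered the pseudocount, the scaling, the depth filter, the fit, the inputs and each replicate left out. Genes were called single-copy-like where the inputs of both aligners differed by less than 0.25 log2, which left 32654 genes, a choice made after seeing the data. A GC correction was not made, since no genome sequence was used.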

Results

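ChIP-seq read depth was measured in inflorescences for 2 methylation reporters and for SUVH9, in wild-type plants and in plants labelled as methylation mutants. The Bowtie set held mCG_WT (n = 2), mCHH_WT (n = 2), WT input (n = 2), mCHH_drm2 (n = 1) and mCHH_drm1drm2cmt2cmt3 (n = 1). The Bowtie2 set held WT input (n = 2 after summing), MBD_WT (n = 1 after summing), SUVH9_WT (n = 2), SUVH9_d2c2 (n = 1) and its input (n = 1). Mean nuclear depth was 7.53 and 6.995 in mCG_WT, 10.6 and 8.89 in mCHH_WT, and 14.9 and 17.3 in the Bowtie inputs. It was 6.18 in mCHH_drm2 and 2.69 in the quadruple mutant, where reads covered 11.6% of bases. In the Bowtie2 set it was 11.8 and 10.0 in the inputs, 26.0 in MBD_WT, 13.2 and 12.6 in SUVH9_WT, 10.8 in SUVH9_d2c2 and 8.26 in its input. Despite that depth, reads covered 93.7% and 89.8% of bases in SUVH9_WT, against 99.7% and 99.6% in the inputs. Over single-copy bins the SUVH9_WT libraries differed by 6.32 times counting noise, so comparisons with them rest on uneven coverage.

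The library labelled mCHH_cmt2 had the same depth as mCG_WT replicate 2 at 93.1% of the bases compared. Their depth steps correlated at 0.98, so no cmt2 comparison was made. Outside the compared bins the files can differ: the densest 1% of bins held 33.8% of depth in mCG_WT replicate 2 and 17.3% in mCHH_cmt2. The 2 files labelled MBD_WT differed by about the sampling noise, with a variance of 0.996 times counting noise, and were counted as 1 sample. That variance alone cannot tell a split library from close ones, since SUVH9_d2c2 and its input had 1.049. The depth steps of the MBD_WT files correlated at 0.189, the highest value outside the pairs taken to share reads, against 0.009 for SUVH9_d2c2 and its input. The Bowtie2 inputs are titled with 1 reporter and carry the other in their genotype entry. The input titled CG had a depth of 4.68 over a pair of MBD6 windows and the input titled CHH had 1.10, so titles were used.

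The genes from which the reporters derive were examined first, as depth over the median protein-coding gene. Over SUVH9 the mCHH_WT libraries had 1.91 and 1.99 and the input titled CHH 1.56, against 1.33 and 1.34 in mCG_WT and 1.09 in the input titled CG. Over the MBD6 windows, which were chosen after their values were seen, the mCG_WT libraries had 4.06 and 5.11, against 1.38 and 1.51 in mCHH_WT. The library labelled mCHH_drm2, with the CHH reporter, had 2.49 there and 3.04 over SUVH9, while the quadruple mutant is too sparse for values of single genes. The library labelled MBD_WT had 1.02 over the MBD6 windows and 1.99 over SUVH9, which goes against its label of the CG reporter. The libraries labelled SUVH9_WT had 1.59 and 0.741 over SUVH9, and the second value is below that of every input. Replicate 2 was also below every input over MBD6 (0.753), HTR5 (1.26) and ENODL17 (0.613). It was above every input over DRM1 (1.57) and CMT3 (1.31). Its low depth over SUVH9 is thus not particular to that gene and cannot settle the label. The library labelled SUVH9_d2c2 had 1.84 over SUVH9 and its input 1.75. In the library labelled mCHH_drm2 the longest run without reads was 1051 bp in DRM1, at the end of a longer interval with few reads, and 77 bp in DRM2. An insertion leaves the depth of a gene in place, so depth over DRM2 and CMT2 checks nothing about insertion alleles.

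**Figure D1:**
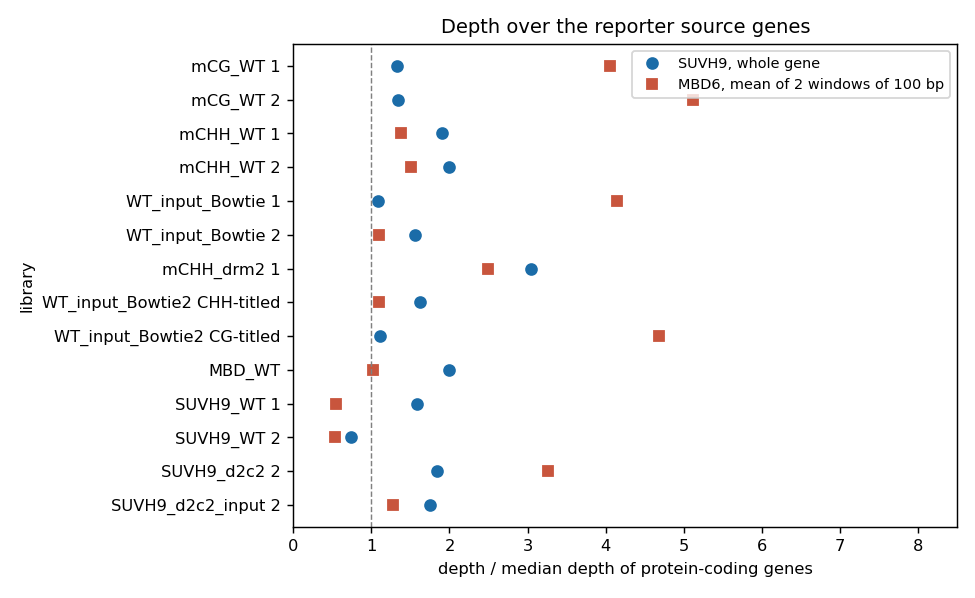
Depth over SUVH9 (circles) and over a pair of MBD6 windows (squares) per library, as a ratio to the median protein-coding gene. MBD_WT sits at 1.99 for SUVH9 and 1.02 for MBD6, while mCG_WT sits at 4.06 and 5.11 for MBD6.

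Where the CG reporter exceeded input was asked by comparing mCG_WT with WT input. HSP70 (AT3G12580) was higher by 1.92 (SE 0.15, n = 2 against 2, adjusted p = 0.021), with a log2 depth of 1.62 ± 0.17 (SD) in mCG_WT and -0.30 ± 0.28 in input. AT1G59860 was higher by 1.82, HSP101 (AT1G74310) by 1.79, HSP90.1 (AT5G52640) by 1.61, BAG6 (AT2G46240) by 1.59 (SE 0.09, adjusted p = 0.015) and HSFA2 (AT2G26150) by 1.55. AT5G48570 and AT1G07135 were higher by 1.48 and 1.47. Among 37622 genes, limma called 119 higher and 5 lower, and the 119 included 90 of 27329 protein-coding genes and 0 of 3866 pseudogenes. The lower calls, chosen after their values were seen, were MIR399a (-1.53), AT5G04695 (-1.11), AT2G08800 (-0.90), AT5G04075 (-0.67) and AT2G08230 (-0.66), all of them short noncoding genes. Genes with heat shock in their names, a group chosen after seeing the data, made 12 of the 90 calls from 60 genes, with no test since these calls prompted the choice. A fit of the 2 groups alone called 0 genes (3089 at an unadjusted p under 0.05) and single-copy-like genes gave 16 calls. Inputs with the alignments by both aligners averaged per library gave 10334, a count that includes the difference between aligners. Without either input limma called 0 genes (1587 and 1617 at an unadjusted p under 0.05), and it called 21 without mCG_WT replicate 2 and 199 without mCG_WT replicate 1.

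For the CHH reporter, mCHH_WT was compared with the same inputs. ERD15 (AT2G41430) was higher by 2.06 (SE 0.09, n = 2 against 2, adjusted p = 0.0038), with a log2 depth of 1.99 ± 0.02 (SD) against -0.06 ± 0.01 in input. AT2G41105, which is not single-copy-like, was higher by 1.98, DIC2 (AT4G24570) by 1.93, AT1G07135 by 1.90, NHL3 (AT5G06320) by 1.82, TCH4 (AT5G57560) by 1.79, AT4G32020 by 1.78 and AT1G32920 by 1.69. All these protein-coding genes also stood above the WT inputs in both mCG_WT libraries, from 0.98 (DIC2) to 1.64 (AT1G07135). None of them is among the genes named as differing between the reporters. The pseudogenes AT2G10405, AT2G10605 and AT1G30390 were higher by 1.11, 0.67 and 0.60, the first and last also not single-copy-like. limma called 413 genes higher and 2 lower, the latter being U6.11p (-1.84) and AT2G06725 (-0.63), chosen after their values were seen. The higher calls included 234 protein-coding genes, 94 of 599 tRNA genes, 31 of 82 snRNA genes and 4 pseudogenes. Heat shock named genes made 2 of the 234 calls. Single-copy-like genes gave 133 calls and the fit of the 2 groups alone 659. The inputs averaged over both aligners gave 5670, which again includes the difference between aligners. No gene was called by limma without any 1 of the 4 libraries (0 calls each), with 1829 to 3396 genes at an unadjusted p under 0.05, against 3721 with all of them.

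**Figure D2:**
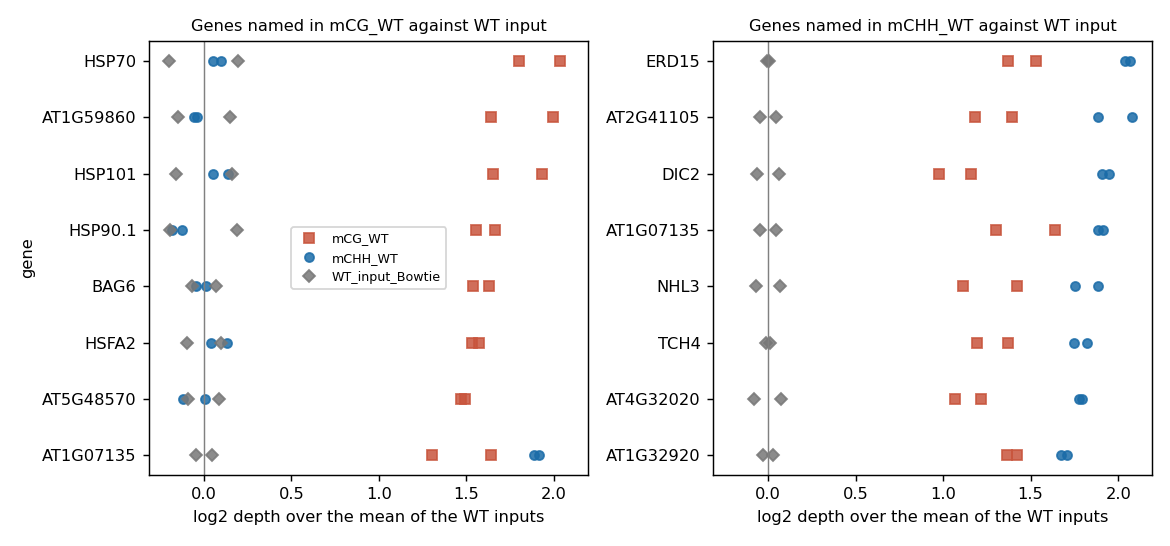
Log2 depth over the mean of the WT inputs for the genes named in each comparison, 1 symbol per library. HSP70 reaches 1.801 and 2.04 in mCG_WT against 0.10 and 0.05 in mCHH_WT, while ERD15 reaches 1.37 and 1.53 in mCG_WT and 2.04 and 2.07 in mCHH_WT.

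The reporters were compared with each other without input, since the series sets CG against non-CG binding proteins. AT1G59860 was higher in mCG_WT by 1.86, HSP70 by 1.85 (SE 0.15, n = 2 against 2, adjusted p = 0.044), HSP90.1 by 1.76, HSP101 by 1.69, BAG6 by 1.60 (SE 0.09, adjusted p = 0.028), AT5G48570 by 1.54, HSFA2 by 1.46 and HSP17.4 by 1.31. GRP7 (AT2G21660) was lower in mCG_WT by -1.20, MYB73 (AT4G37260) by -0.94, CAB1 (AT1G29930, not single-copy-like) by -0.93 and AT5G21940 by -0.85. HSP70 stood at -0.22 ± 0.03 (SD) in mCHH_WT and -0.30 ± 0.28 in input, and GRP7 at 1.06 ± 0.18 in mCHH_WT. limma called 18 genes higher and 14 lower, or 56.2% higher, and 5561 genes had an unadjusted p under 0.05. Scaling to the median protein-coding gene left 5 calls, 80.0% of them higher, and limma called 0 in a fit of the 2 groups alone (4043 at an unadjusted p under 0.05), with a replicate block (3808), with crossed numbers (4032) and in single-copy-like genes (4714). Heat shock named genes made 6 of 16 protein-coding calls that were higher in mCG_WT, from the same mCG_WT libraries. The count was 213 without mCG_WT replicate 2, 20 without mCG_WT replicate 1 and 0 without either mCHH_WT library (4313 and 3752 at an unadjusted p under 0.05).

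The fixed lists were tested in these 3 fits. UBQ10 was higher by 0.85 in mCG_WT (adjusted p = 0.033) and by 1.11 in mCHH_WT (adjusted p = 0.0073), and EF1ALPHA was higher by 0.58 in mCHH_WT (adjusted p = 0.041). Of 14 housekeeping genes, 1 was called higher in mCG_WT and 1 when adjusted over the list alone (camera adjusted p = 0.081). In mCHH_WT 2 were called and 3 when adjusted over the list alone (camera adjusted p = 8.7e-05, adjusted p = 0.33 with an estimated correlation). ATCOPIA4 was the member of the 11 silenced loci called in mCHH_WT when adjusted over the list alone (0.43, 0 over all genes, camera adjusted p = 0.31). Floral regulators had a median of -0.11 in mCHH_WT (camera adjusted p = 0.0044, adjusted p = 0.32 with an estimated correlation), imprinted genes -0.09 (0.024, adjusted p = 0.43 with an estimated correlation) and ONSEN 0.16 (0.024, adjusted p = 0.47 with an estimated correlation), with 0 calls in each. Among reporter source genes SUVH9 was higher by 0.53 and HTR5 by 0.54 in mCHH_WT, called when adjusted over the list alone (2) and not over all genes (0, camera adjusted p = 0.31). HTR5 is on this list but was not taken as the source of either methylation reporter. Depth over the median protein-coding gene was 1.09 over SUVH9 in the input titled CG and 1.56 in that titled CHH. For HTR5 it was 2.43 and 1.64, so the size of each rise depends on the input used. HTR5 was higher by 0.61 in mCG_WT (1 call adjusted over the list alone, camera adjusted p = 0.081). The methylation machinery had medians of 0.01 in mCG_WT and -0.03 in mCHH_WT with 0 calls.

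Between the reporters, the machinery list (median 0.06), the floral regulators (0.06) and the housekeeping genes (-0.12) each had a camera adjusted p of 0.038. With an estimated correlation these were adjusted p = 0.64, adjusted p = 0.50 and adjusted p = 0.64. MBD6 was higher in mCG_WT by 0.61 and SUVH9 lower by -0.53. Each was called when adjusted over the 3 reporter source genes alone, but not when adjusted over the 23 machinery genes, which include both (0 calls), nor over all genes (adjusted p = 0.14 and 0.22).

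The libraries labelled SUVH9_WT were compared with WT input to ask where SUVH9-VENUS binds. Low depth over SUVH9, seen over other genes too, does not settle the label of replicate 2. AT1G40086 was higher by 1.53 (SE 0.15, n = 2 against 2, adjusted p = 0.037), with a log2 depth of 1.19 ± 0.14 (SD) in SUVH9_WT and -0.35 ± 0.05 in input. AT1G40090 was higher by 1.47, AT1G32000 by 1.28, AT1G39070 by 1.23, AT3G43290 by 1.20, AT5G29070 by 1.18, MEE38 (AT3G43160) by 1.17, or -0.35 with all WT inputs, and AT3G43150 by 1.16. Pseudogenes AT4G07917, AT2G06165, AT4G05597, AT5G32485 and AT4G07920 were higher by 1.51, 1.44, 1.37, 1.35 and 1.34. The largest falls among protein-coding genes were AT4G00955 (-2.18), RALFL34 (AT5G67070, -2.01), AT3G50850 (-1.99), AT2G05830 (-1.93) and AT3G44380 (-1.93), followed by AT5G44060 (-1.92), AT3G55820 (-1.91) and AT5G03700 (-1.87). Pseudogenes AT3G60930 (-2.77), AT3G60935 (-2.49), SADHU7-1 (-1.70), AT2G12020 (-1.63, or 0.080 over the d2c2 input) and SADHU2-1 (-1.41) were lower. Not single-copy-like among these are AT1G40086, AT1G40090, AT1G32000, AT1G39070, MEE38, AT4G00955, AT2G05830, AT2G06165, AT4G05597, AT5G32485, AT3G60930, AT3G60935 and AT2G12020. limma called 2090 of 37643 genes higher and 5931 lower. These included 1399 pseudogenes higher and 29 lower, and 494 protein-coding genes higher and 4772 lower. The median of all genes was -0.21 and moved to 0.04 under scaling to the median protein-coding gene, where 4298 were higher and 1652 lower (72.2% higher against 26.1%). With the d2c2 input in place of the WT inputs limma called 0 genes (1301 at an unadjusted p under 0.05), and also 0 without either WT input (4815 and 5472), against 25023 and 21299 without SUVH9_WT replicate 1 or 2.

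Among the lists in the libraries labelled SUVH9_WT, pseudogenes had a median of 0.50, with 2095 higher and 52 lower when adjusted over the list alone (camera adjusted p = 1.7e-72, adjusted p = 0.27 with an estimated correlation). CAC1 (0.72) and HIUN (0.57) were the silenced loci called higher over all genes, and 3 were called when adjusted over the list alone (camera adjusted p = 0.18). ONSEN had a median of 0.29 (camera adjusted p = 0.0016, adjusted p = 0.27 with an estimated correlation), with 1 member lower (1 when adjusted over the list alone). Housekeeping genes had a median of -0.50, with 6 lower over all genes and 12 when adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.49 with an estimated correlation). ACT7 was lower by -0.72 and EF1ALPHA by -0.99. MBD6 was lower by -1.04 (adjusted p = 0.037). As depth over the median protein-coding gene it had 0.752 and 0.753 in SUVH9_WT. The input titled CG had 1.63 and that titled CHH 1.19, so the size of this fall depends on the input used. Imprinted genes (median 0.04), floral regulators (-0.07) and the machinery (-0.06) had camera adjusted p of 0.19, 0.40 and 0.25.

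The library labelled MBD_WT was set against the WT inputs without a test, as 1 library. AT1G25112 was higher by 1.73, AT1G48953 by 1.70, AT1G25025 by 1.53, AT5G15420 by 1.44 and AGO3 (AT1G31290) by 1.30. AT2G05830 (-1.50), AT4G00955 (-1.10), AT5G63150 (-0.96), EMB1793 (-0.88) and AT2G37190 (-0.79) were lower. Pseudogene AT2G10405 was higher by 1.99 and AT2G12020 lower by -1.45. Not single-copy-like among these are AT1G25112, AT1G48953, AT1G25025, AT2G05830, AT4G00955, AT2G10405 and AT2G12020. The silenced loci had a median of 0.29, at percentile 99.5 of random lists (-0.10 to 0.21), led by APOLO (0.95) and ATCOPIA4 (0.92). Over the d2c2 input their median was 0.03, at percentile 76.3, with APOLO at 0.80 and ATCOPIA4 at 0.70. ONSEN had a median of 0.31 over the WT inputs and 0.04 over the d2c2 input. Housekeeping, floral, machinery, imprinted and reporter source lists had medians of -0.24, -0.14, -0.07, 0.04 and -0.45 over the WT inputs. The floral list lay at percentile 0.11 of random lists (-0.10 to 0.05), but at percentile 22.4 over the d2c2 input (median -0.08).

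The library labelled MBD_WT was also set against the libraries labelled SUVH9_WT (n = 1 against 2), where pull-down reagents differ. AT1G48953 was higher by 2.42, RPS28 by 2.04, LHCA2 by 2.01, AT5G15420 by 1.99 and AT1G32225 by 1.81, and pseudogenes AT2G10405, AT3G19045, AT3G60930, AT3G60935 and AT1G17390 by 2.88, 2.61, 2.59, 2.12 and 1.87. AT1G40090 (-1.28), AT1G40086 (-1.23), AT1G39070 (-1.11), IPS1 (-1.07) and AT5G36980 (-0.92) were lower. Lower pseudogenes included AT4G06708 (-0.86) and AT5G31702 (-0.83). Not single-copy-like among these are AT1G48953, RPS28, AT1G32225, AT1G40090, AT1G40086, AT1G39070, AT4G06708 and all the higher pseudogenes named here. Housekeeping genes had a median of 0.31 and the reporter source genes 0.51, against 0.12 over all genes.

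Region classes were compared per library as mean log2 over the WT inputs. Pseudogenes exceeded protein-coding genes by 0.01 ± 0.00 (SD, n = 2) in mCG_WT and by 0.02 ± 0.01 (SD, n = 2) in mCHH_WT. As summed depths the mCG_WT value was -0.005. The excess was 0.71 ± 0.19 (SD, n = 2) in the libraries labelled SUVH9_WT, 0.54 in MBD_WT, 0.39 in SUVH9_d2c2 and 0.39 in the d2c2 input, which had no pull-down. For SUVH9_WT the exact two-sided permutation p was 0.333, the smallest that 2 against 2 libraries allow. Over the d2c2 input the excess of SUVH9_WT was 0.32 ± 0.19 (SD, n = 2) and that of MBD_WT 0.14. Over the WT inputs of both aligners together it was 0.40 in SUVH9_WT, 0.23 in MBD_WT, 0.31 in mCG_WT and 0.33 in mCHH_WT. There each group is set partly against inputs of the other aligner, which hold the same reads. These values therefore include the difference between aligners at pseudogenes and do not measure enrichment by the reporters. Pericentromeric genes exceeded protein-coding genes by 0.65 ± 0.16 in SUVH9_WT, 0.48 in MBD_WT, 0.00 in mCG_WT and 0.02 in mCHH_WT. Over the d2c2 input the values were 0.29 ± 0.16 in SUVH9_WT and 0.12 in MBD_WT. The pericentromeric class holds more pseudogenes than protein-coding genes on every chromosome, so it overlaps the pseudogene class and is not a separate result. The 1 kb flanks of protein-coding genes differed from the genes by -0.16 ± 0.05 in SUVH9_WT (-0.06 ± 0.05 over the d2c2 input), 0.01 ± 0.01 in mCG_WT and 0.01 ± 0.03 in mCHH_WT.

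**Figure D3:**
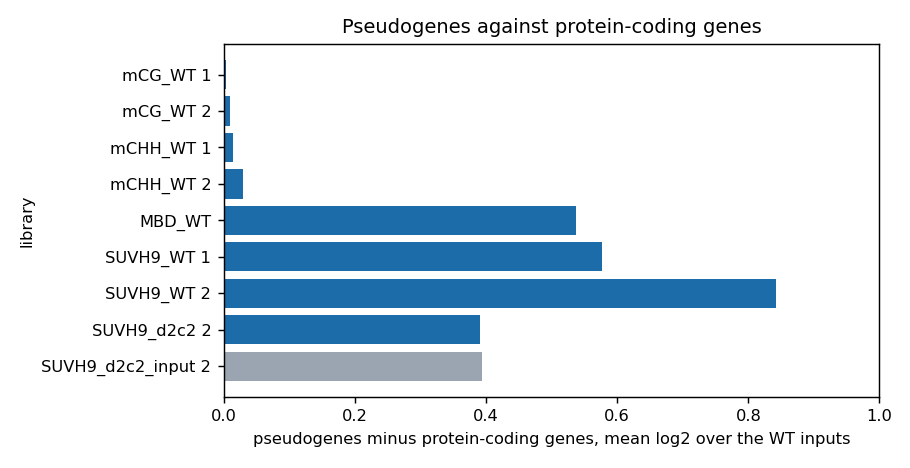
Mean log2 depth over the WT inputs of pseudogenes minus that of protein-coding genes, 1 bar per library, with the d2c2 input in grey. The bars reach 0.58 and 0.84 in SUVH9_WT and 0.39 in the d2c2 input.

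The mutants were compared with mCHH_WT to ask how the CHH reporter depends on the methyltransferases. Target genes were the 200 protein-coding genes highest over input in 1 mCHH_WT replicate, measured against the other replicate. Targets were not selected for a difference from mCG_WT. In the library labelled mCHH_drm2 they changed by -0.93 and -0.89, outside the random ranges of 0.17 to 0.32 and 0.15 to 0.30, while the median of all genes was 0.55. Relative to all protein-coding genes the change was -1.48. Over input the targets stood at 0.94 and 0.90 in the measured mCHH_WT replicate, and at 0.04 and 0.04 in mCHH_drm2. Relative to all protein-coding genes over input, they stood at 0.95 and 0.89 in mCHH_WT and at -0.54 and -0.53 in mCHH_drm2. Random lists were matched on input depth only, so any library without the mCHH_WT pattern would fall at these targets. For neither mutant can the fall separate an effect of the mutations from other differences of the library. The whole library labelled mCHH_drm2 stands apart: its log2 values over input correlated with mCHH_WT at -0.15 and -0.16 across 32652 genes. They correlated with the libraries labelled SUVH9_WT at 0.60 and 0.62, with SUVH9_d2c2 at 0.54 and with MBD_WT at 0.44. With the d2c2 input, which had no pull-down, the value was 0.51, and with mCG_WT 0.06 and 0.04. The mCHH_WT replicates correlated at 0.57. All these values share the reads of the WT inputs as reference, which by itself can raise such correlations. The densest 1% of bins held 10.98% of the depth of mCHH_drm2, against 32.3% and 32.0% in mCHH_WT. Pseudogene targets chosen in the same way rose by 0.74 and 0.61, below the random ranges of 0.89 to 1.04 and 0.81 to 0.97 for pseudogenes. AT1G32920 differed by -2.38, ERD15 by -2.34 and AT4G32020 by -2.31 among single-copy-like genes, and ENODL17 (-3.10) and AT5G15360 (-2.28) lay in an interval of chromosome 5 with few reads in this library. AT4G31430 was higher by 2.91, GRXS17 by 2.54, AT3G31430 by 1.94, AT4G08593 by 1.92 and ROXY1 by 1.82. ONSEN copies (median -4.89) and LpxC3 and LpxC4 (each -5.36) were lower, at repeats where the depth of the Bowtie files depends on their alignment: over the ONSEN copy AT1G11265 mCHH_WT had 6.42 and 6.80, the Bowtie inputs 5.92 and 5.93, the Bowtie2 inputs 1.07 each, and the library labelled mCHH_drm2 0.014. Housekeeping genes had a median of -0.05 (percentile 1.26), or 0.27 (percentile 16.3) for the 11 that are single-copy-like, the machinery 0.80, floral regulators 0.74, imprinted genes 0.84 and silenced loci 0.32. In the quadruple mutant the targets changed by -2.07 and -1.74, or -1.41 relative to all protein-coding genes, but 5451 genes had no read, so no gene is named from it.

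**Figure D4:**
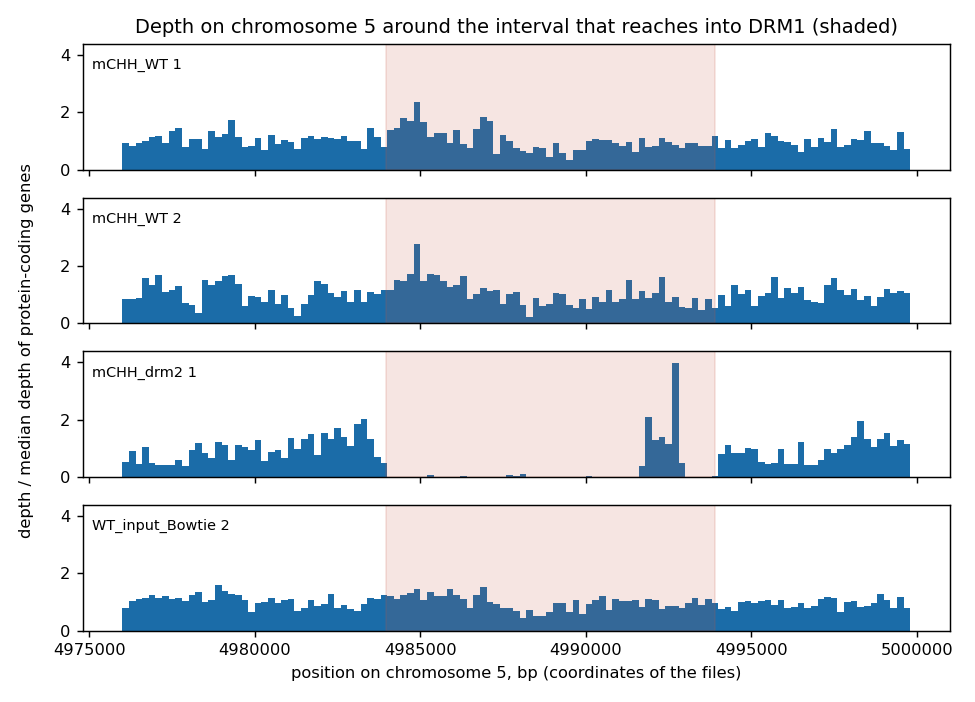
Read depth over the median protein-coding gene in 200 bp steps on chromosome 5, with the interval from 4983978 to 4993917 shaded. In mCHH_drm2, 85.7% of its bases have no read, against 0.614% and 2.64% in mCHH_WT.

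SUVH9_d2c2, whose genotype the labels abbreviate, was compared with the libraries labelled SUVH9_WT to ask whether SUVH9 binding changes in it. DML3 (AT4G34060) was higher by 2.22 and was higher by 2.66 over its own input. AT1G11700 was higher by 1.68, AT2G37580 by 1.60, AT2G13660 by 1.59 and RHA2A by 1.45. AT1G40086 (-1.35), AT1G40090 (-1.20), AT1G39070 (-1.17), AT1G39060 (-1.12) and AT5G35660 (-0.89) were lower, all but the last not single-copy-like. Pseudogenes AT3G60930 (2.06), AT3G60935 (1.79), SADHU7-1 (1.37), Sadhu4-2 (1.08) and SADHU2-1 (0.96) were higher, and AT1G58040 (-1.03) and AT5G32485 (-0.95) lower. Pseudogene targets chosen in 1 SUVH9_WT replicate changed by -0.37 and -0.09 against the other, beside random ranges of -0.30 to -0.22 and -0.08 to -0.0048. In single-copy-like genes the second value (-0.0669) lay inside its range (-0.0683 to 0.0089). Protein-coding targets changed by -0.18 and -0.08, outside -0.03 to 0.08 and -0.01 to 0.09. Here too any library without the SUVH9_WT pattern would fall at the targets. Pseudogenes as a class differed by -0.32 relative to protein-coding genes, by -0.45 without SUVH9_WT replicate 1 and by -0.19 without replicate 2. Against its own input SUVH9_d2c2 showed 0.00 for that class, and protein-coding targets were at 0.01 and 0.00. Beyond DML3, VIM1 was at 0.68 and AT1G02550 at 0.73 over the own input. ONSEN had a median of 0.04 (percentile 0.98) against SUVH9_WT, and housekeeping genes 0.41 (percentile 77.1).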

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

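All tests in this part were chosen only after the result was seen.

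MBD6 stood above the WT inputs in both mCG_WT libraries (0.18 and 0.46) and below them in the library labelled MBD_WT (-0.536), although both are labelled with the CG reporter. Over the CHH-titled input alone MBD_WT was at -0.32 and over the CG-titled input at -0.75, and the difference was not tested. The mCG_WT libraries were at 0.33 and 0.61 over the CHH-titled input. Over the CG-titled input they were at 0.04 and 0.31, so replicate 1 was nearly level with it. The MBD_WT library had 1.02 over the MBD6 windows (1.021 before rounding), which argues against a line with the CG reporter as labelled. Its depth over SUVH9 was 1.99 (1.993), so a line with a SUVH9-derived reporter under another label may be the source. The windows are not specific to the CG label, since SUVH9_d2c2 had 3.26 (its input 1.27) and mCHH_drm2 2.49.

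The library labelled mCHH_drm2 had no read at 85.744% of bases of chromosome 5 from 4983978 to 4993917, an interval of 9940 bp that holds ENODL17 and AT5G15360 and reaches into DRM1, where 1550 of 3578 bases have no read. The other libraries had up to 9.38% there, except the quadruple mutant (86.3%), where most bases have no read anywhere. AT4G31430 had 5.624 times the median protein-coding depth in the same library. The library labelled mCHH_cmt2 was equal to mCG_WT replicate 2 at 93.1328% of the bases compared. These came from data outside the tested comparisons, and no biological explanation was tested.

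Genes higher in mCG_WT than in mCHH_WT had a median difference of 1.27 over 18 genes. Reads shared between copies are argued against, since the aligners differed by -0.021 at these genes. Extra copies in the plants of the mCG libraries stay open: the input titled CG exceeded that titled CHH by 0.188, which is small beside 1.27, but there is 1 input per reporter. Binding of the CG reporter itself cannot be told apart from other causes, since the library labelled MBD_WT was at -0.192 and its label is in doubt.

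Pseudogenes were higher in the libraries labelled SUVH9_WT and in the library labelled MBD_WT than in the WT inputs. Reads placed at several copies are argued against, since SUVH9_WT kept 0.619 in single-copy-like genes. A difference between the WT inputs and the later library preparation may account for part, since the d2c2 input without pull-down reached 0.393. Recovery of methylated DNA by the pull-down stays open: SUVH9_WT exceeded the d2c2 input by 0.316, and that is 1 input of another genotype.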

How the results depend on the processing

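Tests on single-copy-like genes, with crossed replicate numbers, with the MBD_WT files as 2 libraries, and of classes over all WT inputs and of classes and MBD_WT over the d2c2 input, were chosen only after seeing the data; the others were chosen before the data were examined. With a fit of the 2 groups alone limma called 0 genes for mCG_WT against input (3089 at an unadjusted p under 0.05), 659 for mCHH_WT and 0 between the reporters (4043). A replicate block gave 0 between the reporters (3808), as did crossed numbers (0, 4032). All WT inputs, the same reads from both aligners averaged into 2 libraries, gave 10334, 5670 and 2350 calls for mCG_WT, mCHH_WT and SUVH9_WT. These counts include the difference between aligners, since each group is set partly against inputs of the other aligner. Single-copy-like genes gave 16, 133 and 0 calls for mCG_WT, mCHH_WT and the reporters (4714 unadjusted). Median scaling left 5 calls between the reporters. Leaving out 1 library gave 0 to 199 calls for mCG_WT (0 without either input, 1587 and 1617 unadjusted), 0 for mCHH_WT (1829 to 3396 unadjusted), 0 to 213 between the reporters (0 without either mCHH_WT library, 4313 and 3752 unadjusted) and 0 to 25023 for SUVH9_WT (21299 without replicate 2), where a lone sample is assumed to vary like the other groups. Without either WT input SUVH9_WT gave 0 (4815 and 5472 unadjusted), and with the d2c2 input in place 0 (1301 unadjusted). With the MBD_WT files as 2 libraries SUVH9_WT gave 15756 calls, and MBD_WT against SUVH9_WT gave 5607, or 1 with a replicate block. MEE38 reversed to -0.35 with all WT inputs and AT2G12020 to 0.080 over the d2c2 input. The pseudogene excess in mCG_WT was -0.005 as a ratio of summed depths and 0.001 in single-copy-like genes, and that in mCHH_WT was 0.0034 as summed depths. In SUVH9_WT it was 0.32 over the d2c2 input and 0.58 to 0.84 over the WT inputs of the same aligner. With all WT inputs, and so with the difference between aligners included, it was 0.31 in mCG_WT, 0.33 in mCHH_WT and 0.40 in SUVH9_WT. In MBD_WT it was 0.61 for summed depths, 0.54 for median scaling, 0.53 without the filter, 0.49 in single-copy-like genes, 0.37 and 0.59 at pseudocounts of 0.5 and 0.02, 0.23 with all WT inputs and 0.14 over the d2c2 input. Targets in mCHH_drm2 were at -1.64 for summed depths. Apart from the aligner difference with all WT inputs, the cause was not tested where counts moved. Among named genes with a library left out, 21 of 32 values for mCG_WT, 44 of 44 for mCHH_WT, 32 of 48 between the reporters and 52 of 104 for SUVH9_WT were no longer called, in the same direction, as with other settings were 10 of 64, 2 of 85, 57 of 107 and 32 of 247. GC correction was not run, also not with the replicate block, since no genome was used, and SUVH9_WT and input share no pairing for a block. Fits of MBD_WT had 1 library, so alternatives of the fit were not run. With each mCHH_WT replicate in turn not measured, targets in mCHH_drm2 were at -1.52 and -1.45. In the quadruple mutant reads cover 11.6% of bases at a mean depth of 2.69, with 39.3% of depth in the densest 1% of bins, so single genes were not named. With the means of the inputs and the spread pooled over mCG_WT, mCHH_WT and inputs, simulated shifts of 0.3 log2 were recovered in 0 of 50 genes. The simulated noise was independent between genes, so a shift of a whole library was not covered.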

Other observations

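UBQ10 was higher than input in mCG_WT, in mCHH_WT and in SUVH9_d2c2 (0.62 over its own input), as was HTR5 in SUVH9_d2c2 (0.61). In SUVH9_WT (-0.16 and -0.25) and in the library labelled MBD_WT (-0.13) it lay near the median of all genes (-0.21 and -0.10). The 8 genes named as higher in mCG_WT than in mCHH_WT were above the WT inputs by 0.45 (AT1G59860) to 0.87 (AT5G48570) in the library labelled mCHH_drm2, where the median of all genes against mCHH_WT was 0.55. ERD15 was at -0.28 and TCH4 at 0.03 in that library.

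Chloroplast reads made 34.1% and 33.5% of the depth in the Bowtie2 WT inputs, 16.0% in the files labelled MBD_WT, 3.604% and 2.37% in SUVH9_WT and 7.53% in both SUVH9_d2c2 and its input. SUVH9_d2c2 differed from its input by 1.049 times counting noise over single-copy bins.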
